A study of Mus musculus with 45 samples.

How the data were processed

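RNA of NIH-3T3 cells, a mouse embryonic fibroblast line, was measured on 45 Affymetrix arrays in 11 groups. Per the labels, cells of passages 5 to 15 were seeded to cover 40% of the plate on the day before and had reached about 80% when the experiment was started with fresh medium with 4-thiouridine (4sU) or actinomycin D. Total RNA (tc) was taken before and after 1 h and 2 h of 5 µg/ml actinomycin D. Newly transcribed RNA (nt) carried the 4sU label after 15 min or 30 min at 500 µM or 60 min at 200 µM, and total RNA was also measured at 30 min and 60 min. Unlabelled pre-existing RNA (p) was measured at 60 min. A second 60 min experiment carries the label 2F, which the labels do not explain, nor do they explain the word mock, which is in the titles of the 15 min and 60 min samples and not of those at 30 min. Each group had 3 arrays, except 9 each for newly transcribed and total RNA at 30 min.

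RNA was extracted with Trizol and labelled with the one-cycle protocol, per the labels. The deposited values were intensities processed with GCRMA, per the submitters' processing notes, whose version is not stated. Their log2 was taken here. All 31451 probe sets were read, 61 control probe sets were kept out of the tests, and 25031 of the remaining 31390 had exactly 1 gene symbol in the platform annotation, for 13232 genes. Symbols were checked through the Entrez identifiers of the RefSeq table, which matched 24934 probe sets and changed 0 symbols. Arrays carry no read depth, and their number limits the precision.

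Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the arrays of the experiment, group as the only factor) for probe sets with a mean log2 of 5 or more, an intensity of 32. The filter is on the mean over arrays, so a group can lie below it, and detection calls were not used here. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 over all probe sets tested and a fold change of 2 or more. The 14 comparisons comprised actinomycin D at 1 h and 2 h against untreated cells and against each other, newly transcribed against total RNA in the 3 experiments that hold both, pre-existing against total and against newly transcribed RNA, the difference of the enrichment between experiments as interaction terms, newly transcribed RNA at 15 min and 60 min against 30 min, and total RNA of labelled cells against untreated cells. Actinomycin D and the pre-existing fraction answer which transcripts decay, and the newly transcribed fraction answers which are made fastest relative to their amount.

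Named genes followed a rule: the 10 largest called increases and decreases, or 5 in the secondary comparisons, with a mean log2 of 7 or more, 1 symbol, no overlap between groups and the probe set of the highest mean over all arrays. This last condition on overlap was dropped for differences between experiments. Up to 4 members with the largest changes were added per gene list described, and Fos, Myc and Actb served as reference points. Gapdh was read only from control probe sets. Probe sets called in a comparison with 5 or fewer calls were named whatever their intensity.

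The 24 gene lists were immediate-early genes, feedback regulators, cytokines and growth factors, other transcription factors, Zfp zinc fingers, p53 targets, the integrated stress and unfolded protein response, heat shock, interferon response, ribosomal proteins, oxidative phosphorylation, glycolysis and citrate cycle, proteasome, matrix and cytoskeleton, mitosis, G1/S and replication, regulators of apoptosis, sterol synthesis, splicing factors, small nucleolar RNA hosts and nuclear RNAs, replication-dependent histones, and markers of epithelial cells, leukocytes, and endothelium and muscle. They were written from general knowledge, and 8 genes are in more than 1 list. Lists with 5 or more measured genes were tested with limma's camera at its preset correlation of 0.01, 1 probe set per gene, adjusted over the lists of a comparison. The estimated correlation and fry were alternatives.

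Half-lives came from linear ratios of group means at a mean log2 of 7 or more. The line of p/tc on nt/tc set the scale at which newly transcribed and pre-existing RNA add up to total RNA, and the half-life followed from the new fraction after 60 min by exponential decay (the labelling time times ln 2, divided by the negative logarithm of the fraction that was not new), which assumes constant total RNA during labelling. The 95% intervals came from limma's interval of the nt/tc change. Enrichment was compared between experiments by Spearman correlation across probe sets.

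No label states that a replicate number marks a shared culture. Deviations of same-numbered arrays from their group means correlated above 0.1 in every pair for actinomycin D at 1 h (0.143 to 0.183) and 2 h (0.259 to 0.576), nt/tc (0.149 to 0.299) and p/tc (0.219 to 0.391) at 60 min, newly transcribed RNA at 60 min against 30 min (0.195 to 0.303) and total RNA at 60 min against untreated cells (0.122 to 0.330), so for these a fit with a replicate block was weighed. This pairing rests on the data alone.

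On simulated data with 200 changed probe sets and the spread of the real arrays, a change of 1.5 log2 was recovered for 94.0% after 2 h of actinomycin D, 98.5% for nt/tc at 30 min, 38.8% at 60 min and 97.0% in the 2F arrays. It was recovered for 14.9% and 52.2% in the differences of 2F and of 30 min from 60 min, 86.6% for 15 min against 30 min and 85.1% for total RNA at 30 min against untreated cells. No comparison made more than 7 false calls. A change of 0.5 log2 was never called, being below the fold threshold.

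Alternatives covered the filter, thresholds, centring on the array median, quantile normalization, an intensity trend, all arrays in 1 fit, 1 probe set per gene, probe sets that match several transcripts left out, a replicate block and leaving out each array. Arrays dropped for their 3' to 5' values and sets among the 30 min arrays were added after the data were examined. Other groupings of the arrays were counted for up to 100 splits. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and the robust line used MASS 7.3.60.0.1. Genome positions were not used. Probe sets without a symbol were tested but described only as a group.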

Results

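Transcript turnover in growing NIH-3T3 mouse fibroblasts was read from the deposited GCRMA intensities of 45 Affymetrix arrays, by blocking transcription with actinomycin D and by separating newly transcribed RNA, labelled with 4-thiouridine, from total and unlabelled pre-existing RNA. Changes are log2 fold changes ± standard error from limma between groups of 3 arrays, or 9 arrays each for newly transcribed and total RNA at 30 min. A change was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold change of 2 or more. The comparisons, thresholds, gene lists and rules for naming genes were fixed before the data were examined. Nothing states that replicates are separate cultures, so p measures the spread between arrays, which may be technical.

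Within 1 h of actinomycin D, most immediate-early genes measured fell, as did some feedback regulators, transcription factors and stress genes. Dusp1, a phosphatase that switches off MAP kinases, fell by 4.46 ± 0.24, and Myc, a growth-promoting transcription factor, fell by 3.16 ± 0.19. Nfil3, a basic leucine zipper repressor, fell by 3.29 ± 0.16, and Socs3, which damps cytokine receptors, fell by 2.87 ± 0.26. Adjusted p reached at most 1.6e-04 for these genes (3 arrays per group). Of 15060 probe sets tested, 539 fell and 387 rose, which covered 324 and 57 genes. The values of the groups did not overlap for 49.9% of probe sets, against 10% by chance.

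Of 32 immediate-early genes, 24 fell, 0 rose and 8 did not pass (camera adjusted p = 1.3e-14, adjusted p = 0.16 with an estimated correlation). The median of the list was -1.43. Its losses included Dusp5 (-3.34 ± 0.21) and Dusp6 (-2.86 ± 0.30), further MAP kinase phosphatases, the zinc-finger factor Egr1 (-2.59 ± 0.16) and the AP-1 subunit Jun (-1.89 ± 0.18). Feedback regulators fell for 8 of 20 genes, 9 when adjusted over the list alone (camera adjusted p = 2.7e-10, adjusted p = 0.16 with an estimated correlation). Nfkbia, the inhibitor of NF-kappaB, fell by 2.05 ± 0.15, and the receptor kinase antagonists Spry1 and Spry2 fell by 1.82 ± 0.29 and 1.74 ± 0.20. Among 44 transcription factors 8 fell, 9 adjusted over the list alone (camera adjusted p = 1.9e-09, adjusted p = 0.16 with an estimated correlation), with Irf1 at -2.09 ± 0.20. Of 134 zinc-finger genes of the Zfp family 17 fell and 2 rose (camera adjusted p = 1.8e-06, adjusted p = 0.24 with an estimated correlation), led by Zfp212 (-1.88 ± 0.10) and Zfp719 (-1.71 ± 0.18). 

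The integrated stress and unfolded protein response lost 6 of 21 genes (camera adjusted p = 0.0054, adjusted p = 0.25 with an estimated correlation), led by the glutathione-degrading enzyme Chac1 (-2.71 ± 0.18) and Ppp1r15a (-1.87 ± 0.19), a phosphatase subunit that restores translation. Of 14 small nucleolar RNA hosts and nuclear RNAs 3 fell (camera adjusted p = 0.011, adjusted p = 0.45 with an estimated correlation), with Snhg5 at -1.62 ± 0.15. Other large losses were Ier5 (-2.41 ± 0.12), the serum-induced kinase Sgk1 (-2.18 ± 0.16), the cAMP phosphodiesterase Pde4b (-2.28 ± 0.26) and Clk1 (-1.93 ± 0.11), a kinase of splicing factors. In the matrix and cytoskeleton list 2 of 47 genes fell, the collagen chains Col1a1 (-2.04 ± 0.21) and Col6a1 (-1.07 ± 0.14), and the list median was -0.24 (camera adjusted p = 8.7e-04, adjusted p = 0.45 with an estimated correlation). Probe sets that were low only at 1 h also differed between arrays not given the drug. No gene was called among 71 of oxidative phosphorylation or 35 of the proteasome, yet these lists were shifted upward, with medians of 0.22 (camera adjusted p = 2.5e-04, adjusted p = 0.45 with an estimated correlation) and 0.23 (camera adjusted p = 8.2e-04, adjusted p = 0.45 with an estimated correlation). The highest log2 change of any probe set was 2.52. Among named genes with a mean log2 of 7 or more, the largest increase was that of the cold-inducible RNA-binding protein Cirbp, by 2.83-fold (adjusted p = 0.0011). Of other such genes, the alcohol dehydrogenase Adh7 rose by 1.37 ± 0.19, the clathrin adaptor subunit Ap1s2 by 1.25 ± 0.20 and the interferon-induced tetherin Bst2 by 1.10 ± 0.18. Actb, the cytoskeletal actin used as a reference point, was not called (-0.10 ± 0.09). Counts adjusted over the list alone were otherwise the same as those over all genes. Sizes and ranks are uncertain for Dusp1, Nfil3, Dusp5 and Spry1, whose level was below an intensity of 32 in at least 1 group.

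At 2 h the losses had deepened and spread, and almost no transcript rose. Dusp1 fell by 6.82 ± 0.24, Chac1 by 5.87 ± 0.18, Myc by 5.38 ± 0.19 and Dusp6 by 5.10 ± 0.30 relative to untreated cells. Ccn1, a matricellular protein, fell by 4.96 ± 0.30, and Cdc42ep2, an effector of the GTPase Cdc42, by 4.75 ± 0.12. The polo-like kinase Plk2 fell by 4.68 ± 0.27 and the transcriptional coregulator Cited2 by 4.54 ± 0.17. None of these had an adjusted p above 1.6e-06 (3 arrays per group).

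Probe sets called lower numbered 1419 (888 genes) and those called higher 81 (24 genes) of 15060 tested, so 5.40% of the calls were increases, against 20.3% after quantile normalization. Among immediate-early genes 25 of 32 fell and 0 rose (camera adjusted p = 3.3e-16, adjusted p = 0.058 with an estimated correlation). Feedback regulators fell for 17 of 20 (camera adjusted p = 1.4e-14, adjusted p = 0.058 with an estimated correlation), including Socs3 (-4.55 ± 0.26), Spry2 (-4.37 ± 0.20), Nfkbia (-3.53 ± 0.15) and Id2 (-3.40 ± 0.14), a dominant-negative partner of basic helix-loop-helix factors. Of 134 Zfp genes 61 fell (camera adjusted p = 5.6e-16, adjusted p = 0.058 with an estimated correlation), among them Zfp746 (-3.29 ± 0.34) and Zfp407 (-3.15 ± 0.14). Transcription factors fell for 19 of 44 (camera adjusted p = 1.1e-11, adjusted p = 0.075 with an estimated correlation), with Snai2, a repressor of epithelial genes, at -4.33 ± 0.31 and Cebpd at -3.34 ± 0.14. The list medians were -2.50 for immediate-early genes, -2.40 for feedback regulators, -0.92 for Zfp genes and -0.80 for transcription factors. 

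Stress genes fell for 8 of 21 (camera adjusted p = 0.0073, adjusted p = 0.21 with an estimated correlation), including Sesn2 (-3.13 ± 0.30) and the pseudokinase Trib3 (-2.95 ± 0.17). Small nucleolar RNA hosts fell for 5 of 14 (camera adjusted p = 0.0073, adjusted p = 0.33 with an estimated correlation), with Snhg5 at -2.40 ± 0.15. Single members fell in lists that did not shift as a whole: Mdm2, the ubiquitin ligase of p53 (-1.41 ± 0.14), the chaperone Dnajb1 (-1.97 ± 0.18), the replication licensing factor Cdt1 (-2.34 ± 0.19), the mitotic kinase Aurka (-1.46 ± 0.11), the survival factor Mcl1 (-2.77 ± 0.13) and the angiogenic factor Vegfa (-1.61 ± 0.13). The counts behind them were 4 of 16 p53 targets, 1 of 13 heat-shock genes, 3 of 26 genes of DNA replication, 1 of 29 mitotic genes, 4 of 19 regulators of apoptosis and 2 of 13 cytokines. The list tests gave camera adjusted p = 0.21, 0.38, 0.35, 0.34, 0.11 and 0.93 in that order. The cytokine list had a median of 0.19 and a mean of -0.11, so its average rested on few members. Splicing factors fell for 3 of 30 (camera adjusted p = 0.064), including Clk1 (-3.02 ± 0.11) and Clk4 (-1.86 ± 0.23). No gene of sterol synthesis, none of 41 ribosomal proteins and none of 28 of glycolysis and the citrate cycle was called, with medians of -0.04, 0.01 and 0.17, the first 2 of which changed sign with the scaling of the arrays. Only the last of these lists was shifted (camera adjusted p = 0.029, adjusted p = 0.12 with an estimated correlation). Oxidative phosphorylation again lay above the other genes at a median of 0.22 (camera adjusted p = 1.1e-05, adjusted p = 0.33 with an estimated correlation), as did the proteasome at 0.17 (camera adjusted p = 0.038, adjusted p = 0.56 with an estimated correlation). Among 7 interferon-response genes Ifit1 fell (-1.06 ± 0.29). The rising genes of adequate intensity were Cirbp (1.57 ± 0.21) and Haghl (1.12 ± 0.11). Counts adjusted over the list alone were the same throughout. In at least 1 group Dusp1, Chac1, Myc, Dusp6, Socs3, Spry2, Zfp746, Zfp407, Sesn2 and Ifit1 lay below an intensity of 32, which leaves the size of the change uncertain.

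Between 1 h and 2 h feedback regulators and Zfp genes fell, while a group of transcripts that had been low at 1 h was higher again. These probe sets also differed between arrays of labelled cells not given the drug, with a median of -1.04 between total RNA replicates 3 and 1 at 60 min, against -0.11 for all probe sets, so their course was not shown to be a response to the drug. Ccn1 fell by 3.69 ± 0.30, Snai2 by 3.59 ± 0.31, Cited2 by 3.27 ± 0.17 and Arid5b by 3.00 ± 0.21. Vat1 rose by 2.09 ± 0.29, the transcriptional corepressor Tle5 by 1.94 ± 0.23, Cnot3, a subunit of the deadenylase complex, by 1.89 ± 0.30 and the endocytic GTPase Dnm1 by 1.83 ± 0.27. Among these genes the adjusted p was at most 0.0011 (3 arrays per group). Of 1446 calls 1103 were lower and 343 higher, so 23.7% were increases, against 39.7% after quantile normalization. Col1a1 (1.81 ± 0.21) and Col6a1 (1.25 ± 0.14), low at 1 h, were among those that rose, and the matrix list had 3 genes higher and 1 lower of 47 (camera adjusted p = 6.6e-05, adjusted p = 0.54 with an estimated correlation). Feedback regulators fell for 12 of 20 (camera adjusted p = 1.1e-07, adjusted p = 0.29 with an estimated correlation), including Id3 (-2.68 ± 0.15) and Errfi1 (-2.03 ± 0.11), and Zfp genes for 35 of 134 (camera adjusted p = 4.4e-08, adjusted p = 0.29 with an estimated correlation). Adjusted over the list alone these counts were the same. The level of Arid5b and Id3 was below an intensity of 32 in at least 1 group, so the size of the change and its rank are uncertain.

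After 30 min of 4-thiouridine, newly transcribed RNA was enriched in the transcripts that actinomycin D depleted and poor in those of mitochondria, metabolism and the proteasome. Gadd45g was higher than in total RNA by 3.68 ± 0.19, Plk3 by 3.56 ± 0.26 and Arc by 3.54 ± 0.31. Urod, an enzyme of haem synthesis, was lower by 3.19 ± 0.08, the peroxidase Gpx4 by 3.16 ± 0.20 and the mitochondrial membrane protein Tspo by 3.16 ± 0.15. The largest adjusted p among these was 1.8e-09 (9 arrays per group). Of 16044 probe sets 3804 were higher and 4112 lower, covering 1187 and 2391 genes by the probe set taken for each gene. The groups did not overlap for 53% of probe sets.

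All 41 immediate-early genes measured were higher, with a median of 2.54 (camera adjusted p = 3.0e-21, adjusted p = 0.025 with an estimated correlation), among them Klf6 (3.40 ± 0.15), Atf3 (3.29 ± 0.22) and Fos (2.73 ± 0.11). Feedback regulators were higher for 21 of 26 (camera adjusted p = 1.2e-10, adjusted p = 0.038 with an estimated correlation), such as Tnfaip3, which restrains NF-kappaB (3.61 ± 0.30), and the Notch target Hes1 (3.40 ± 0.33). Cytokines were higher for 14 and lower for 2 of 17 (camera adjusted p = 2.6e-06, adjusted p = 0.025 with an estimated correlation), with Lif at 3.42 ± 0.28 and Il6 at 2.93 ± 0.69. Transcription factors were higher for 26 of 50 (camera adjusted p = 6.7e-10, adjusted p = 0.025 with an estimated correlation), including Myc (2.77 ± 0.15) and Runx1 (2.70 ± 0.30), and Zfp genes for 94 of 173 with 7 lower (camera adjusted p = 2.4e-17, adjusted p = 0.039 with an estimated correlation). Small nucleolar RNA hosts and nuclear RNAs were higher for 11 of 14 (camera adjusted p = 2.8e-06, adjusted p = 0.025 with an estimated correlation), among them Snhg7 (3.14 ± 0.20) and Neat1 (2.07 ± 0.13), the scaffold of paraspeckles. Stress genes (10 higher and 3 lower of 20, camera adjusted p = 0.0027, adjusted p = 0.11 with an estimated correlation) and p53 targets (6 higher and 1 lower of 17, camera adjusted p = 0.017, adjusted p = 0.17 with an estimated correlation) leaned the same way, with Ppp1r15a at 2.55 ± 0.21, Btg2 at 3.23 ± 0.16 and Mdm2 at 1.69 ± 0.08. 

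On the other side, 66 of 70 genes of oxidative phosphorylation were lower, with a median of -1.89 (camera adjusted p = 3.9e-15, adjusted p = 0.036 with an estimated correlation), including the ATP synthase subunit Atp5o (-3.06 ± 0.11) and the succinate dehydrogenase subunit Sdhb (-2.94 ± 0.13). The exception was Cox7c, a cytochrome oxidase subunit, at 4.78 ± 0.31. Its probe set had an intensity of only 23.5 before actinomycin D, and whether it detects the mature transcript was not tested. Glycolysis and the citrate cycle were lower for 22 of 28 (camera adjusted p = 1.6e-05, adjusted p = 0.025 with an estimated correlation), with Idh2 at -2.64 ± 0.13, and the proteasome for 25 of 35 (camera adjusted p = 3.8e-07, adjusted p = 0.025 with an estimated correlation), with Psmd8 at -2.33 ± 0.15. Ribosomal proteins were split, 10 lower and 3 higher of 41 (camera adjusted p = 5.7e-04, adjusted p = 0.22 with an estimated correlation), with Rpl14 at -2.25 ± 0.10 and Rpl12 at 3.34 ± 0.14. Splicing factors were higher for 5 and lower for 1 of 30 (camera adjusted p = 0.0016, adjusted p = 0.1 with an estimated correlation), led by Clk1 (2.72 ± 0.17). Matrix genes were lower for 13 of 47 with 3 higher (camera adjusted p = 0.29), with Col6a2 at -1.90 ± 0.12 and Myl6 at 2.57 ± 0.17. Actb was at 0.52 ± 0.06, short of the fold threshold. The counts adjusted over the list alone were the same for every list here. Sizes and ranks are uncertain for Tnfaip3, Hes1 and Cox7c, whose level was below an intensity of 32 in at least 1 group.

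At 60 min immediate-early genes were again enriched and oxidative phosphorylation depleted, with larger errors. Junb, an AP-1 subunit, was higher in newly transcribed RNA by 4.24 ± 0.66, Nfil3 by 3.68 ± 0.30, the bromodomain protein Brd2 by 3.66 ± 0.53 and Id1 by 3.68 ± 0.57. The fatty acid oxidation enzyme Ech1 was lower by 4.15 ± 0.38, Tspo by 4.74 ± 0.31, the glutathione transferase Mgst1 by 4.38 ± 0.46 and Lamtor2, which anchors growth signalling to lysosomes, by 4.02 ± 0.33. Adjusted p reached at most 7.8e-04 for these genes (3 arrays per group). Of 15411 probe sets 2727 were higher and 3361 lower (1295 and 2039 genes), and 49.6% did not overlap. The total RNA arrays of this group resembled each other less than elsewhere, with median correlations of 0.904 to 0.947, and replicate 1 of the newly transcribed RNA had 0.861. This array also had the highest Gapdh 3' minus 5' signal of all arrays, 3.07.

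All 40 immediate-early genes measured were higher, with a median of 2.78 (camera adjusted p = 7.3e-21, adjusted p = 0.068 with an estimated correlation), including Btg2 (4.79 ± 1.21), Ier2 (4.46 ± 0.88), the clock gene Per1 (4.39 ± 0.55) and Fos (2.70 ± 0.39). Feedback regulators were higher for 19 of 26 (camera adjusted p = 4.4e-10, adjusted p = 0.068 with an estimated correlation), with Hes1 at 4.14 ± 0.44 and Id3 at 3.38 ± 0.63. Transcription factors were higher for 29 of 50 (camera adjusted p = 4.4e-10, adjusted p = 0.014 with an estimated correlation), with Cebpb at 3.46 ± 0.71, Klf5 at 3.44 ± 0.52 and Myc at 3.24 ± 0.33. Zfp genes were higher for 67 and lower for 9 of 158 (camera adjusted p = 2.1e-11, adjusted p = 0.068 with an estimated correlation), with Zfp217 at 3.76 ± 0.36, and cytokines higher for 13 and lower for 1 of 17 (camera adjusted p = 2.7e-06, adjusted p = 0.068 with an estimated correlation), with Inhba at 2.59 ± 0.33. Small nucleolar RNA hosts were higher for 9 of 14, 10 adjusted over the list alone (camera adjusted p = 8.6e-05, adjusted p = 0.068 with an estimated correlation). Among 17 p53 targets 8 were higher, such as Cdkn1a, an inhibitor of cyclin-dependent kinases (2.55 ± 0.33), and 2 lower (camera adjusted p = 0.03, adjusted p = 0.085 with an estimated correlation). 

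Oxidative phosphorylation was lower for 62 of 72 genes, 63 adjusted over the list alone with 1 higher, at a median of -1.79 (camera adjusted p = 8.5e-14, adjusted p = 0.068 with an estimated correlation). Ndufc1 (-3.19 ± 0.28) and Ndufc2 (-2.77 ± 0.30), subunits of complex I, were furthest down. Mitotic genes were lower for 12 of 29 (camera adjusted p = 0.011, adjusted p = 0.085 with an estimated correlation), including Ccnb2, a cyclin that drives mitosis (-2.92 ± 0.29), and Bub1, a kinase of the spindle checkpoint (-2.27 ± 0.44). The proteasome was lower for 18 of 35 (camera adjusted p = 6.9e-05, adjusted p = 0.074 with an estimated correlation), and glycolysis and the citrate cycle for 15 of 28, 16 adjusted over the list alone (camera adjusted p = 7.5e-04, adjusted p = 0.068 with an estimated correlation), with Mdh1 at -3.04 ± 0.47. Of 6 interferon-response genes 4 were lower, Gbp2 (-2.07 ± 0.36) and B2m (-1.70 ± 0.22) among them, though the list as a whole did not shift (camera adjusted p = 0.22). Actb was not called (0.86 ± 0.23). For transcription factors 1 gene was lower when adjusted over the list alone, and the other counts were unchanged. In at least 1 group Ech1, Mgst1, Lamtor2, Hes1 and Zfp217 lay below an intensity of 32, which leaves the size of the change uncertain.

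Pre-existing RNA, unlabelled after 60 min, held less of some regulatory transcripts than total RNA. Tnfaip3 was lower by 2.44 ± 0.29, Skil, a repressor of TGF-beta signalling, by 2.45 ± 0.32, the cyclin Ccnt2 by 2.67 ± 0.37 and Taf1d, a factor of RNA polymerase I, by 3.37 ± 0.32. Cth, which makes cysteine, was higher by 2.03 ± 0.26, the mitochondrial enzyme Pck2 by 2.20 ± 0.51, the transcription factor Atf5 by 2.14 ± 0.50 and the glycine transporter Slc6a9 by 1.59 ± 0.41. None of these had an adjusted p above 0.041 (3 arrays per group). Of 15411 probe sets 1072 were lower and 288 higher (233 and 155 genes). The median over all probe sets was 0.11, and -0.02 after each array was centred on its median. Leaving out single arrays changed the count of 1360 calls to 777, 879 and 848 without replicates 1, 2 and 3 of pre-existing RNA, to 2684 without replicate 1 of total RNA and to 2135 without replicate 1 of newly transcribed RNA.

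Immediate-early genes were lower for 11 of 40, 14 adjusted over the list alone (camera adjusted p = 1.6e-08, adjusted p = 0.21 with an estimated correlation), among them Klf10 (-2.38 ± 0.26), Egr1 (-1.61 ± 0.24), Fos (-1.55 ± 0.39) and Klf4 (-1.55 ± 0.30). Feedback regulators were lower for 8 of 26, 10 adjusted over the list alone (camera adjusted p = 3.5e-08, adjusted p = 0.15 with an estimated correlation), with Errfi1, an inhibitor of the EGF receptor, at -1.79 ± 0.24 and Spry2 at -1.67 ± 0.39. Zfp genes were lower for 10 of 158, 8 adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.21 with an estimated correlation), with Zfp568 at -2.61 ± 0.38. Cytokines were lower for 6 of 17 (camera adjusted p = 1.5e-05, adjusted p = 0.15 with an estimated correlation), including Lif (-2.22 ± 0.23) and Ereg, a ligand of the EGF receptor (-1.94 ± 0.29). Transcription factors were lower for 5 of 50, 6 adjusted over the list alone (camera adjusted p = 0.0088, adjusted p = 0.15 with an estimated correlation), led by Klf7 (-2.35 ± 0.29), and small nucleolar RNA hosts for 5 of 14 (camera adjusted p = 0.0099, adjusted p = 0.21 with an estimated correlation), led by Kcnq1ot1 (-1.70 ± 0.32). The thymidylate synthase Tyms (-2.20 ± 0.27) and Cdt1 (-1.23 ± 0.32) were lower among 27 replication genes (camera adjusted p = 0.023, adjusted p = 0.28 with an estimated correlation). Stress genes were higher for 2 of 20, 4 adjusted over the list alone (camera adjusted p = 0.0088, adjusted p = 0.15 with an estimated correlation), with Trib3 at 2.57 ± 0.39. Among the total RNA arrays of this comparison, replicate 2 had an Actb 3' minus 5' signal of 3.08, against a median of 0.77 over all arrays. Oxidative phosphorylation had a median of 0.40 with 1 gene higher, 0 adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.55 with an estimated correlation). Myc (0.02 ± 0.33) and Actb (0.02 ± 0.23) were not called, and the sign of these values depended on the scaling. Against the total RNA of the 2F arrays, a comparison chosen after the data were examined, Cth (0.16), Pck2 (0.24), Atf5 (0.14), Slc6a9 (0.39) and Trib3 (-0.03) were not called, and Myc was lower by 1.58. The stress list changed direction there, to -0.24 (-0.33 to -0.06 over resampled genes) relative to all genes. Klf4 (-0.93) and Cdt1 (-0.43) were also not called there, nor was the replication list. The level of Tnfaip3, Zfp568 and Tyms was below an intensity of 32 in at least 1 group, so the size of the change and its rank are uncertain.

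Setting newly transcribed against pre-existing RNA widened the division further. Tnfaip3 was higher in newly transcribed RNA by 5.48 ± 0.29, Lif by 5.40 ± 0.23, Klf10 by 4.73 ± 0.26 and Fos by 4.25 ± 0.39, while Vwa5a was lower by 5.79 ± 0.31, Lamtor2 by 5.11 ± 0.33 and Ech1 by 5.06 ± 0.38. Among these genes the adjusted p was at most 1.3e-05 (3 arrays per group). Of 15411 probe sets 3437 were higher and 4714 lower, and 70.6% did not overlap. All 40 immediate-early genes (camera adjusted p = 6.5e-21, adjusted p = 0.072 with an estimated correlation) and 24 of 26 feedback regulators (camera adjusted p = 4.8e-12, adjusted p = 0.045 with an estimated correlation) were higher, against 66 of 72 genes of oxidative phosphorylation that were lower (camera adjusted p = 2.3e-12, adjusted p = 0.072 with an estimated correlation). Tyms was at 4.78 ± 0.27 and Cox7c at 4.02 ± 0.68, the latter again apart from its list. Adjusted over the list alone these counts were the same. Sizes and ranks are uncertain for Tnfaip3, Vwa5a, Lamtor2, Ech1, Tyms and Cox7c, whose level was below an intensity of 32 in at least 1 group.

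The 2F arrays, made at the same dose and duration, gave the division with the smallest errors. Their total RNA arrays correlated at 0.996, so repeats of the same sample were not excluded. Prdm2 was higher in newly transcribed RNA by 2.91 ± 0.14, Zbtb7a by 2.82 ± 0.23, Ccnl1 by 2.70 ± 0.10 and Hbegf by 2.59 ± 0.13. Grcc10 was lower by 4.13 ± 0.15, Tspo by 4.04 ± 0.17, Atp5e by 3.93 ± 0.18 and Uqcr11 by 3.84 ± 0.16. The largest adjusted p among these was 3.2e-06 (3 arrays per group). Of 16205 probe sets 3885 were higher and 3534 lower (1574 and 1883 genes), and 85.9% did not overlap.

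All 41 immediate-early genes were higher at a median of 1.96 (camera adjusted p = 1.8e-12, adjusted p = 0.24 with an estimated correlation), with Arc at 2.71 ± 0.24, Gadd45b at 2.25 ± 0.14 and Fos at 2.11 ± 0.23. Feedback regulators were higher for 25 of 26 (camera adjusted p = 4.4e-08, adjusted p = 0.026 with an estimated correlation), with Socs3 at 2.41 ± 0.12, and Zfp genes for 120 with 3 lower of 175 (camera adjusted p = 2.8e-14, adjusted p = 0.026 with an estimated correlation), with Zfp398 at 2.73 ± 0.18. Transcription factors were higher for 39 of 52 (camera adjusted p = 9.7e-10, adjusted p = 0.026 with an estimated correlation), including Snai1 (2.45 ± 0.13), Klf9 (2.25 ± 0.10) and Myc (1.71 ± 0.11). Cytokines were higher for 14 and lower for 1 of 17 (camera adjusted p = 3.2e-05, adjusted p = 0.076 with an estimated correlation), with Gdnf at 2.69 ± 0.12, and p53 targets higher for 7 of 17 (camera adjusted p = 0.016, adjusted p = 0.24 with an estimated correlation), with Sesn2 at 2.41 ± 0.17. Small nucleolar RNA hosts were higher for 9 of 14 (camera adjusted p = 9.9e-04, adjusted p = 0.16 with an estimated correlation). Among regulators of apoptosis 7 were higher and 4 lower of 20 (camera adjusted p = 0.38), with the pro-apoptotic Bcl2l11 at 2.22 ± 0.10 and Bad at -2.63 ± 0.18.

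Oxidative phosphorylation was lower for 62 and higher for 1 of 70 genes at a median of -2.23 (camera adjusted p = 4.0e-15, adjusted p = 0.29 with an estimated correlation), with Ndufa3 at -3.78 ± 0.12. Glycolysis and the citrate cycle were lower for 18 of 28 (camera adjusted p = 3.9e-06, adjusted p = 0.16 with an estimated correlation), with Tpi1 at -2.70 ± 0.12, and the proteasome for 18 of 35 (camera adjusted p = 4.0e-06, adjusted p = 0.24 with an estimated correlation), with Psmb2 at -2.53 ± 0.09. Ribosomal proteins were lower for 18 and higher for 2 of 42 (camera adjusted p = 6.4e-06, adjusted p = 0.4 with an estimated correlation), with Rps15 at -2.15 ± 0.13 and Rpl12 at 2.19 ± 0.13. Mitotic genes were lower for 11 of 29 (camera adjusted p = 0.0063, adjusted p = 0.2 with an estimated correlation), with Cdca3 at -2.75 ± 0.08 and the centromeric histone Cenpa at -1.99 ± 0.10. Sterol synthesis had 5 genes lower and 3 higher of 18 (camera adjusted p = 0.99), with Ebp at -3.14 ± 0.13 and Stard4, a sterol carrier, at 1.44 ± 0.11. Actb was not called (0.56 ± 0.09). Adjusted over the list alone every count was the same. In at least 1 group Arc, Zfp398 and Gdnf lay below an intensity of 32, which leaves the size of the change uncertain.

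Whether the enrichment of newly transcribed RNA differed between the 2F arrays and the other 60 min arrays was tested directly, and few differences were called, with little power to find them: the self-test recovered 14.9% of differences of 1.5 log2. Limma called 4 of 15879 probe sets, with 2128 at an unadjusted p below 0.05 (3 arrays in each of 4 groups). The called probe sets, chosen after their values were seen, were Sfrp1, an antagonist of Wnt signalling (2.33 ± 0.30, adjusted p = 0.038), 1 without a gene name (2.07 ± 0.27, adjusted p = 0.038), the metalloreductase Steap2 (1.78 ± 0.24, adjusted p = 0.041) and Anxa1, a phospholipid-binding protein (-2.50 ± 0.33, adjusted p = 0.038). All but Steap2 lay below an intensity of 32 in at least 1 group, which leaves the size of the difference uncertain. Of 41 immediate-early genes 0 rose and 0 fell, also when adjusted over the list alone, but the median was -0.73 (camera adjusted p = 3.6e-10, adjusted p = 0.74 with an estimated correlation). The median was -0.38 for oxidative phosphorylation (camera adjusted p = 3.4e-05, adjusted p = 0.74 with an estimated correlation) and -0.30 for ribosomal proteins (camera adjusted p = 3.4e-05, adjusted p = 0.74 with an estimated correlation), again with no gene called. Without replicate 1 of total RNA, newly transcribed RNA replicate 1 or newly transcribed RNA replicate 3 of the 60 min arrays, 306, 170 and 15 probe sets were called. Without total RNA replicate 2 there were 2, and 0 without any other array, with 1286 to 2740 at an unadjusted p below 0.05. Dropping the 2 arrays with high 3' to 5' values, a choice made after the data were examined, gave 623 calls, and fitting all 45 arrays together gave 477. 

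Between 30 min at 500 µM and 60 min at 200 µM, where dose and duration changed together, the enrichment differed for many more probe sets. It was higher at 30 min for Cox7c (3.08 ± 0.74), the catalase gene Cat (3.05 ± 0.60) and the sterol carrier Scp2 (2.54 ± 0.51), and lower for Zbtb7a (-2.77 ± 0.67), the ETS repressor Erf (-2.74 ± 0.74) and Cebpb (-2.66 ± 0.58). Adjusted p reached at most 0.011 for these genes (9 arrays per group at 30 min and 3 at 60 min). Of 15933 probe sets 1672 were higher and 1319 lower, but by the probe set taken for each gene 434 genes were higher and 819 lower. Mitotic genes were higher for 6 and lower for 0 of 29, also adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 1 with an estimated correlation), including Bub1 (1.64 ± 0.36) and Nusap1, which bundles spindle microtubules (1.52 ± 0.34). Fos (0.03 ± 0.30) and Myc (-0.47 ± 0.33) were not called. Without total RNA replicate 2 at 60 min the calls numbered 1379, and without newly transcribed RNA replicate 1 they numbered 1654. When the 30 min arrays were averaged to 3 values per group, limma called 0 probe sets, with 2854 at an unadjusted p below 0.05, so the count depends on each array being a unit of its own. The level of Cox7c and Zbtb7a was below an intensity of 32 in at least 1 group, so the size of the change and its rank are uncertain.

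After 15 min, newly transcribed RNA held less of some regulatory and more of some oxidative phosphorylation transcripts than after 30 min. Atf3 was lower at 15 min by 2.94 ± 0.38, Csrnp1 by 2.90 ± 0.33, Mob3a by 2.75 ± 0.22 and Tnfaip3 by 2.66 ± 0.22. Ppp1r10, a nuclear targeting subunit of a phosphatase, was higher by 2.21 ± 0.38 and Ifi27l2a by 1.95 ± 0.45. None of these had an adjusted p above 0.004 (3 and 9 arrays). Of 16366 probe sets 1710 were higher and 1199 lower, but by the probe set taken for each gene 143 genes were higher and 699 lower. The groups did not overlap for 36.6%. Setting replicates 1, 4 and 7 at 30 min against the other arrays called 2651 probe sets, against 2909 for the real grouping, so the arrays of 30 min are not alike. Oxidative phosphorylation was higher for 25 of 70 genes at a median of 0.87 (camera adjusted p = 3.3e-39, adjusted p = 0.047 with an estimated correlation), with Atp5k at 1.67 ± 0.20 and Ndufa3 at 1.61 ± 0.20. No ribosomal protein was called, but their median was 0.37 (camera adjusted p = 1.8e-17, adjusted p = 0.066 with an estimated correlation). Immediate-early genes were lower for 17 of 41 (camera adjusted p = 4.9e-06, adjusted p = 0.55 with an estimated correlation), feedback regulators for 14 of 26 (camera adjusted p = 1.2e-06, adjusted p = 0.38 with an estimated correlation) and stress genes for 5 of 20 (camera adjusted p = 0.0079, adjusted p = 0.48 with an estimated correlation). Zfp genes were lower for 40 and higher for 1 of 180 (camera adjusted p = 4.1e-04, adjusted p = 0.48 with an estimated correlation), with Zfp646 at -2.28 ± 0.29. Myc was lower by 1.23 ± 0.18, and Fos was not called (-0.36 ± 0.16). Adjusted over the list alone the counts were the same. Sizes and ranks are uncertain for Zfp646, whose level was below an intensity of 32 in at least 1 group.

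Newly transcribed RNA of the 60 min label, compared with that of 30 min, held less of the stress response. The aminotransferase Gpt2 was lower by 3.47 ± 0.34, Trib3 by 2.79 ± 0.31, Cth by 2.63 ± 0.20 and the lipoprotein receptor Vldlr by 2.41 ± 0.21, while Pxdc1 was higher by 2.60 ± 0.27, Lif by 2.42 ± 0.44 and Snai1 by 2.38 ± 0.58. Among these genes the adjusted p was at most 0.0087 (3 and 9 arrays). Of 16082 probe sets 1762 were lower and 784 higher, but by the probe set taken for each gene 390 genes were lower and 452 higher. There were 363 calls of probe sets when arrays of the same replicate number were blocked. Averaging the 30 min arrays to 3 values per group, chosen after the data were examined, left 520. Replicate 1 at 60 min was the array with the Gapdh 3' minus 5' signal of 3.07. Under that block of replicate numbers Lif (2.46), Atf5 (-1.51) and Fos (-1.23) were not called. Stress genes were lower for 9 of 20 (camera adjusted p = 6.2e-08, adjusted p = 0.046 with an estimated correlation), with Chac1 at -2.11 ± 0.37 and Atf5 at -1.48 ± 0.22. Total RNA of the 60 min arrays was also low in the stress list against untreated cells (-0.87 relative to all genes), whereas that of the 2F arrays was at -0.18 (-0.47 to 0.07 over resampled genes). Small nucleolar RNA hosts were lower for 2 of 14 (camera adjusted p = 6.1e-04, adjusted p = 0.052 with an estimated correlation). Fos was lower by 1.35 ± 0.25. Adjusted over the list alone these counts were the same. 

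Total RNA after 30 min of 4-thiouridine in fresh medium held more immediate-early transcripts than the cells sampled before actinomycin D. Fos rose by 4.92 ± 0.15, the zinc-finger factor Egr2 by 4.16 ± 0.41, the orphan receptor Nr4a1 by 3.92 ± 0.18, the RNA-destabilizing protein Zfp36 by 3.40 ± 0.31 and the chemokine Cxcl1 by 3.17 ± 0.39. Txnip, an inhibitor of thioredoxin and glucose uptake, fell by 1.36 ± 0.17, but was not called at -1.42 with a replicate block. The largest adjusted p among these was 9.2e-04 (9 and 3 arrays). Limma called 95 of 15376 probe sets, 72 higher and 23 lower. The 30 min total RNA arrays fell into sets of replicates 1, 4 and 7, of 2, 5 and 8 and of 3, 6 and 9, and setting each of these sets against the remaining arrays called 186, 1004 and 377 probe sets, more than the real grouping. The count was 53 and 60 without replicates 2 and 3 of the cells before actinomycin D. Of 39 immediate-early genes 21 rose, 22 adjusted over the list alone (camera adjusted p = 3.3e-52, adjusted p = 8.9e-05 with an estimated correlation). Cytokines rose for 4 of 15, 7 adjusted over the list alone (camera adjusted p = 1.6e-11, adjusted p = 0.0071 with an estimated correlation), with Ereg at 1.74 ± 0.15, and feedback regulators for 4 of 22 (camera adjusted p = 0.0015, adjusted p = 0.22 with an estimated correlation), with Id1 at 1.70 ± 0.15. No mitotic gene was called, though the median of 29 was -0.30 (camera adjusted p = 1.6e-10, adjusted p = 0.22 with an estimated correlation). Myc (0.58 ± 0.22) and Actb (0.09 ± 0.08) were not called.

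After 60 min some immediate-early genes and cytokines were again higher than before actinomycin D, and some stress genes were lower. Lif rose by 4.89 ± 0.30, Cxcl1 by 4.86 ± 0.19, Il6 by 4.06 ± 0.29 and Tnfaip3 by 3.78 ± 0.21, Egr2 by 4.42 ± 0.35, Egr3 by 3.65 ± 0.22 and Fos by 3.61 ± 0.17. Trib3 fell by 3.61 ± 0.31, Txnip by 2.72 ± 0.37, the transcription factor Sp3 by 2.62 ± 0.39 and Cth by 2.54 ± 0.20. Adjusted p reached at most 0.024 for these genes (3 arrays per group). Of 15364 probe sets 229 rose and 116 fell, 345 in all. This count was 37, 70 and 52 without replicates 1, 2 and 3 of the cells before actinomycin D, and 2371, 684 and 47 without replicates 1, 2 and 3 of total RNA at 60 min. Immediate-early genes rose for 14 and fell for 1 of 38, 20 and 1 adjusted over the list alone (camera adjusted p = 1.1e-16, adjusted p = 0.11 with an estimated correlation), and cytokines rose for 7 of 16, the same adjusted over the list alone (camera adjusted p = 5.8e-10, adjusted p = 0.05 with an estimated correlation). Among 24 feedback regulators 6 rose, or 10 with 1 lower adjusted over the list alone (camera adjusted p = 2.3e-07, adjusted p = 0.05 with an estimated correlation). Stress genes fell for 4 of 20, 6 adjusted over the list alone (camera adjusted p = 5.3e-05, adjusted p = 0.06 with an estimated correlation), with Chac1 at -1.72 ± 0.21. Relative to all genes the stress list was at -0.87 (-1.32 to -0.16), but at -0.18 (-0.47 to 0.07) in total RNA of the 2F arrays, made at the same dose and duration. Genes of sterol synthesis fell for 2 of 18, 3 adjusted over the list alone (camera adjusted p = 4.1e-06, adjusted p = 0.25 with an estimated correlation), with Mvd at -1.68 ± 0.29, not called at -1.68 with a replicate block. Myc (-0.46 ± 0.34) and Actb (-0.19 ± 0.19) were not called. Of the markers of other cell types only 5 of 12 epithelial, 6 of 13 leukocyte and 5 of 11 endothelial and muscle genes had a probe set. Among these, no epithelial, endothelial or muscle marker reached the intensity filter, and of the leukocyte markers only Cd14 did (0.44 ± 0.33, not called). Of the replication-dependent histones only H2ac19 was measured, at 0.64 ± 0.18 after 2 h of actinomycin D, not called. In at least 1 group Lif, Il6 and Tnfaip3 lay below an intensity of 32, which leaves the size of the change uncertain.

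Fos and Myc were enriched in every labelling experiment, and across probe sets the enrichment of newly transcribed RNA ranked transcripts alike. The Spearman correlation of its log2 enrichment was 0.934 between 30 min and the 2F arrays, 0.856 between 60 min and 2F and 0.797 between 30 min and 60 min, with the same sign for 88.1%, 83.2% and 80.4% of probe sets. Enriched transcripts tended to be lost under actinomycin D. The correlation of enrichment with the change at 2 h was -0.606 for 30 min and -0.626 for 60 min, and with the change at 1 h it was -0.226 and -0.433. Dusp1, Myc, Socs3 and Nfil3 are examples that fell with the drug and belong to lists enriched in newly transcribed RNA. No p is given, because genes are not independent of each other.

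Half-lives assume that total RNA was constant during labelling. Against untreated cells, however, the lists of immediate-early genes, cytokines and feedback regulators were shifted upward in total RNA at 60 min. Of their members 14 of 38, 7 of 16 and 6 of 24 were called higher. For genes that rose the values reflect induction as well as decay and are not half-lives proper. Values ran from regulators to metabolism, and their scale was not fixed by the 60 min arrays. In the planned calculation Fos had a half-life of 208 min (95% interval 103 to 397), Myc 136 min (71.2 to 244) and Actb 802 min (552 to 1162). The median over 9047 probe sets was 1732 min, with quartiles of 950 and 2938. The line through the ratios of pre-existing and newly transcribed to total RNA that sets the scale had a correlation of only -0.0881, and the signal of pre-existing RNA was more than 1.5 times that of total RNA for 19.8% of probe sets. Of 15 other ways to compute it, 5 were added after the data were seen, and their medians ran from 73.6 to 11048 min, with no value for 2. A simulated median of 298 min, given the spread of these arrays, came back as 1215 min. In simulations without any true relation, the shared total RNA gave log2 ratios a correlation of 0.50, whereas the observed value was -0.296.

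The 2F arrays of newly transcribed and total RNA, joined to the same pre-existing RNA after the results of the other versions had been seen, gave a median of 346 min (quartiles 189 and 631) over 9530 probe sets. With the line of nt/tc on p/tc the same arrays gave 164 min. Intervals of single genes leave out this uncertainty of scale and take arrays as independent. The line had a correlation of -0.633, 0.860% of probe sets exceeded the limit of 1.5, and a simulated 298 min came back as 338 min. This formula does not hold for genes that rise during labelling, as Fos and Lif may have. By it Fos then had 53.4 min (28.0 to 87.5), Myc 78.9 min (62.1 to 98.6) and Lif 30.1 min (19.7 to 40.8). Socs3 had 38.0 min (25.4 to 52.3), Nfil3 46.4 min (30.1 to 66.1), Clk1 41.8 min (31.5 to 53.2) and Actb 205 min (174 to 240). The loss within 1 h of actinomycin D, taken as decay under a complete block and computed after the data were seen, corresponds to 18.97 min (16.8 to 21.9) for Myc and 18.2 min (16.5 to 20.4) for Nfil3, which was dim at 1 h. Both lie outside the intervals from labelling. For Socs3 at 20.9 min (17.4 to 26.2) and Clk1 at 31.2 min (27.7 to 35.6) the intervals overlap. Longer half-lives were those of B2m at 1363 min (1176 to 1580), Ccnb2 at 1351 min (1083 to 1685) and Rpl14 at 1674 min (1396 to 2008), and the longest among the named genes were Grcc10 at 5799 min (4586 to 7332) and Lamtor2 at 5749 min (4617 to 7157). The list medians went from 63.6 min for immediate-early genes, which were being induced, through 73.3 min for feedback regulators, 92.0 min for cytokines, 100 min for transcription factors and 113 min for both Zfp genes and small nucleolar RNA hosts. Stress genes had 138 min, p53 targets 157, splicing factors 250 and sterol synthesis 272. Matrix genes followed at 326 min, mitotic genes 451, ribosomal proteins 601, the proteasome 628, glycolysis and the citrate cycle 716 and oxidative phosphorylation 1541. With the planned arrays the same lists ranged from 203 min for immediate-early genes to 5187 min for oxidative phosphorylation.

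**Figure D1:**
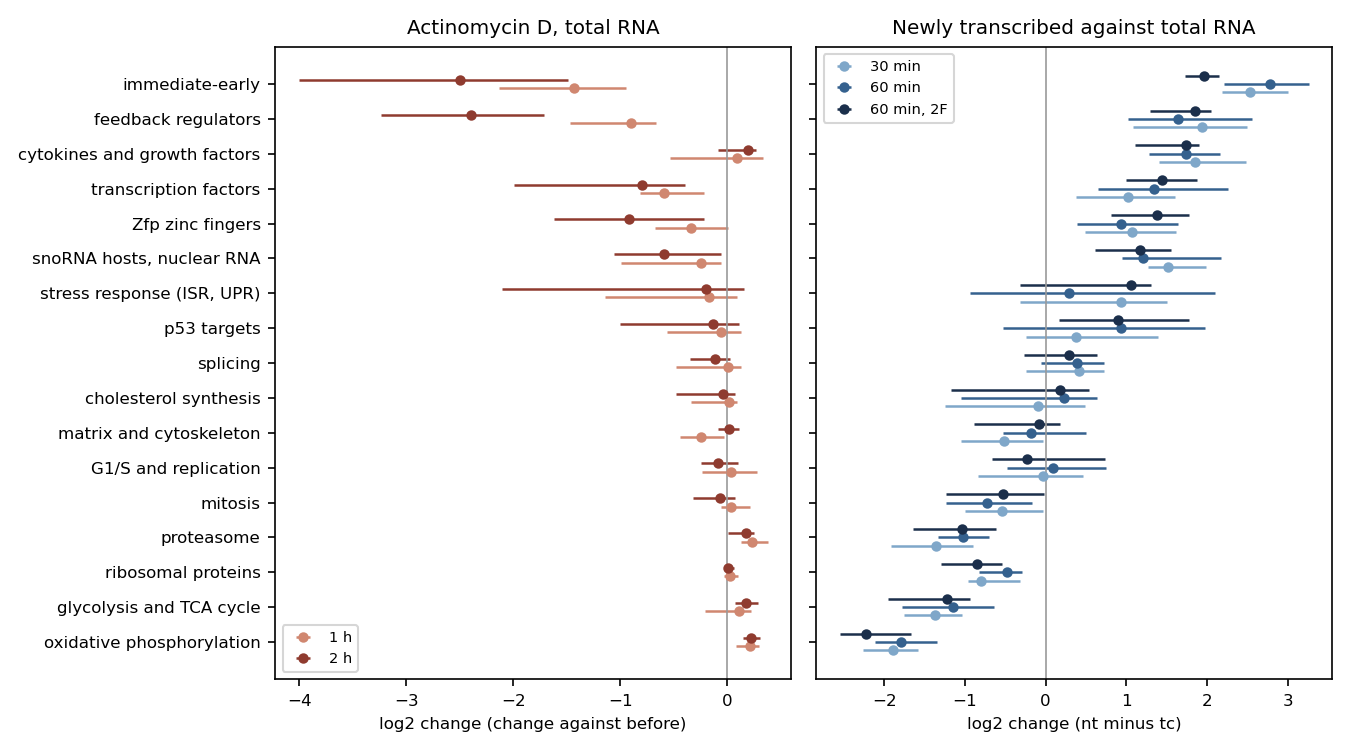
Median log2 fold change of each gene list (points, with lines to the quartiles of its genes) after actinomycin D, left, and in newly transcribed relative to total RNA, right. Immediate-early genes lay at -2.50 after 2 h of the drug and at 2.54 in the 30 min label.

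**Figure D2:**
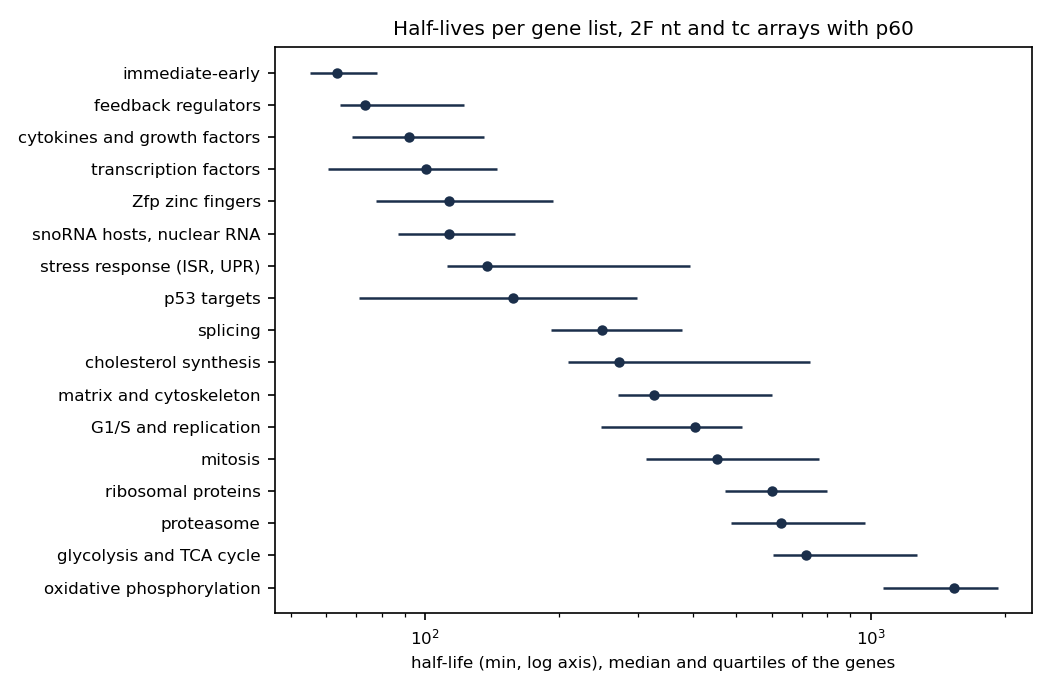
Half-life in minutes on a log axis for each gene list from the 2F arrays, with points at the median and lines to the quartiles of its genes. Total RNA was taken as constant and cell growth was left out. It ran from 63.6 min for immediate-early genes to 1541 min for oxidative phosphorylation.

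**Figure D3:**
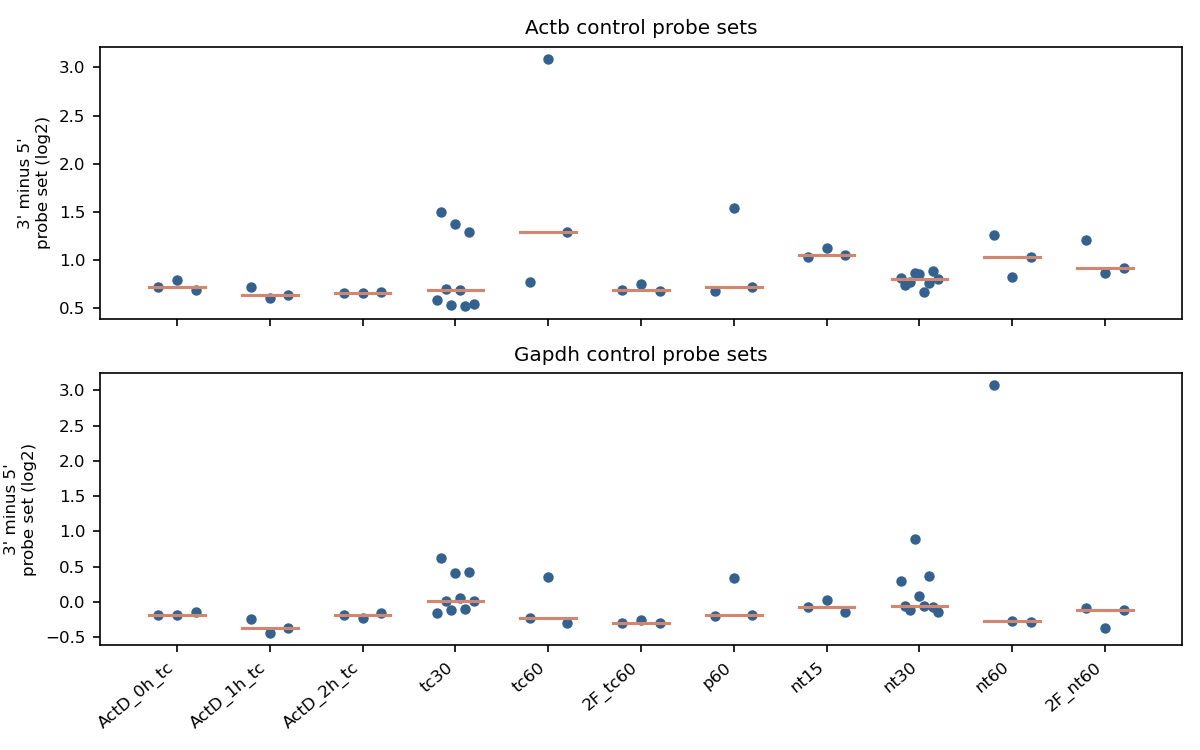
Difference of the 3' and 5' signals (log2) of the Actb and Gapdh control probe sets, with 1 point per array and a line at the median of each group. The highest Actb value, 3.08, belonged to replicate 2 of total RNA at 60 min.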

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

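The splits of the arrays and the tests of the 3 patterns weighed here were chosen only after the results were seen, whereas the differences between experiments were planned.

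The enrichment of newly transcribed RNA differed between experiments by an interaction term for 4 probe sets between the 2F and the other 60 min arrays and for 2991 between 30 min and 60 min. Among named genes the latter difference was 3.08 for Cox7c, 3.05 for Cat, 2.54 for Scp2, 1.64 for Bub1, 1.52 for Nusap1, -2.77 for Zbtb7a, -2.74 for Erf and -2.66 for Cebpb. Of 120 groups of 9 values tested for a value far from the others, 3 had one (2.5%), where chance gives about 1 in 20. Sdhb in total RNA at 30 min was lowest in replicate 9 (10.07 against a median of 10.33, gap of 0.4931 of the range). In newly transcribed RNA at 30 min, replicate 4 was highest for Arc (9.98 against 8.97, gap of 0.547) and for the Gapdh 3' minus 5' value (0.90 against -0.06, gap of 0.502).

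Other splits of the same arrays were counted for each comparison. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real counts and the highest of the others were 926 and 0 for actinomycin D at 1 h, 1500 and 2 at 2 h, 1446 and 0 between these times, 6088 and 0 for nt/tc at 60 min, 1360 and 0 for p/tc, 8151 and 0 for nt/p, 7419 and 0 for 2F, and 345 and 0 for total RNA at 60 min, each with 1 split as large, the real one. With 100 splits drawn for the 2F difference, 1 was as large, the real one (4, highest other 1). Leaving out any 1 of the 2F arrays left 0 calls in limma, with 1286 to 1870 at an unadjusted p below 0.05, and the self-test made 3 false calls in this comparison, so chance was not excluded. In 100 splits of single arrays 1 was also as large, the real one, for nt/tc at 30 min (7916, highest other 3265), the 30 min difference (2991 and 276), 15 min against 30 min (2909 and 2651) and 60 min against 30 min (2546 and 1478). The split with 2651 sets replicates 1, 4 and 7 of newly transcribed RNA at 30 min against the rest, so whether single arrays are independent units is open. With sets of 3 arrays as units the 10 splits are too few, except for the 30 min difference, which then has 0 calls in limma, with 2854 at an unadjusted p below 0.05. For total RNA at 30 min against untreated cells, 2 of 100 were as large (95, highest other 186). Splitting off replicates 2, 5 and 8, outside the draw, called 1004, which points to a structure of the samples. The 30 min total RNA arrays correlated at 0.989 to 0.996 within the sets 1, 4, 7 and 2, 5, 8 and 3, 6, 9 but at 0.926 to 0.971 between them. For newly transcribed RNA at 30 min these values overlapped, at 0.974 to 0.993 and 0.914 to 0.986, and clustering did not give the sets, so they are less certain there. Within each set alone against untreated cells the counts were 240, 1092 and 957.

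Genes of the stress response were higher in pre-existing than in total RNA at 60 min, by 0.37 (0.12 to 0.63) over the median of all genes for 20 genes. Without total RNA replicate 2, whose Actb 3' end signal was far above its 5' end signal, the excess was 0.297 (0.04 to 0.69), so degraded RNA in that array could not be told from other causes by this test. Against the total RNA of the 2F arrays the difference was -0.235 (-0.33 to -0.06), and the pre-existing RNA arrays correlated at 0.922 to 0.954 with those arrays but at 0.764 to 0.926 with the total RNA arrays of their own experiment. With replicate 1 of that total RNA, whose Actb 3' minus 5' value was 0.77, they correlated at 0.915 to 0.926. The lower values thus came from replicates 2 and 3, so array quality may account for them. A candidate explanation is that the pre-existing RNA came from cultures resembling those of the 2F arrays, in which the stress response stood higher than in the other 60 min cultures. No biological explanation was tested.

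After 1 h of actinomycin D 139 probe sets were lower and stood near their starting level at 2 h, with median changes of -1.21 and 0.21. Short-lived transcripts made again would be enriched in newly transcribed RNA, but the median nt/tc at 30 min was -1.43 (-1.67 to -1.21), against 1.90 for the 323 probe sets lower at both times, which argues against it. Across probe sets the deviation at 1 h followed the difference between total RNA replicates 3 and 1 at 60 min, with a Spearman correlation of 0.399, a pair of arrays picked after the data were examined. With the difference between the sets 2, 5, 8 and 1, 4, 7 at 30 min it was 0.292. A difference between arrays that recurs in several groups may therefore lie behind the return of Col1a1 and Cnot3, while which step of the work makes it stays open.

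Probe sets with no gene name were enriched in newly transcribed RNA, with a median nt/tc at 30 min of 2.03 for 1566 against -0.23 for 14038 named ones, and 66.9% against 19.2% called higher. Low intensity as the whole cause was argued against, since within deciles of the level before actinomycin D the difference was still 0.929 (0.80 to 1.03). Unnamed probe sets fell more at 2 h of the drug, by -0.258 (-0.31 to -0.20) within the same deciles, which short-lived or unprocessed RNA would give. Being higher at 15 than 30 min, by 0.81, decides nothing, as oxidative phosphorylation was too. Introns of known genes were not told from other unstable RNA.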

How the results depend on the processing

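The settings with sets of 30 min arrays, with 2 arrays dropped for their 3' to 5' values, with 1 total RNA array at 60 min and with the 2F arrays in place of others were chosen after the data were examined, and the others were planned.

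In all settings named genes never lost or reversed a call in 225 cases and did in 33. Of 103 list results 33 never did. Results not called in the main fit, as for Myc in p/tc, are among these and could not lose a call, so the counts overstate stability. Their sign changes were not counted. Most list losses came with an estimated correlation.

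Counts of calls that moved by more than 1.5 times are given by setting. Removing the filter tests more dim probe sets and gave 1704 for actinomycin D at 1 h, 2488 for actinomycin D at 2 h, 2145 for p/tc and 297 for the 2F difference. Raising it to a mean log2 of 7, which tests fewer, gave 299 for actinomycin D at 1 h, 484 for actinomycin D at 2 h, 531 for actinomycin D at 2 h against 1 h, 4083 for nt/tc at 30 min, 3446 for nt/tc at 60 min, 316 for p/tc, 4379 for nt/p, 4049 for nt/tc in 2F, 1 for the 2F difference, 1385 for the 30 min difference, 1476 for 15 against 30 min, 1265 for 60 against 30 min, 62 for total RNA at 30 min and 178 for total RNA at 60 min. With 1 probe set per gene, which also tests fewer, there were 381 for actinomycin D at 1 h, 912 for actinomycin D at 2 h, 816 for actinomycin D at 2 h against 1 h, 3578 for nt/tc at 30 min, 3379 for nt/tc at 60 min, 254 for p/tc, 4334 for nt/p, 3457 for nt/tc in 2F, 1 for the 2F difference, 1226 for the 30 min difference, 842 for 15 against 30 min, 838 for 60 against 30 min, 50 for total RNA at 30 min and 160 for total RNA at 60 min. Dropping the fold threshold, a looser rule, gave 5469 for actinomycin D at 1 h, 5227 for actinomycin D at 2 h, 5271 for actinomycin D at 2 h against 1 h, 13033 for nt/tc at 30 min, 13533 for nt/tc in 2F, 7439 for 15 against 30 min, 4771 for 60 against 30 min and 308 for total RNA at 30 min. An adjusted p below 0.01, a stricter one, gave 774 for p/tc, 0 for the 2F difference, 1243 for the 30 min difference, 58 for total RNA at 30 min and 71 for total RNA at 60 min, and limma gave 2128 for the 2F difference at an unadjusted p below 0.05. Fitting all 45 arrays together gave 3015 for p/tc, 477 for the 2F difference and 1567 for total RNA at 60 min. The 2F difference fell from 4 to 1 with quantile normalization and to 0 with an intensity trend, with limma giving 2126 at an unadjusted p below 0.05. For these 3 fits the cause was not tested. No other count of calls moved by that much with centring, quantile normalization, an intensity trend or the removal of probe sets that can match several transcripts.

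A replicate block gave 1 for the 2F difference, 363 for 60 against 30 min and 29 for total RNA at 30 min, and the cause was not tested. Where the numbers pair the arrays, it ended the calls of Lif, Atf5 and Fos at 60 against 30 min and of Mvd, and changed no other call of a named gene. Where they do not pair, Txnip in total RNA at 30 min and mitosis in the 30 min difference were not called with the block. Of the comparisons not paired by their numbers, every array correlated best with its own number for actinomycin D at 2 h against 1 h and for nt/tc in 2F, but only 4 of 9 did for nt/tc at 30 min, 1 of 3 for nt/p, 1 of 3 for 15 against 30 min and 2 of 3 for total RNA at 30 min.

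Without total RNA replicate 2 and newly transcribed RNA replicate 1 of the 60 min arrays there were 623 for the 2F difference, 760 for the 30 min difference and 684 for total RNA at 60 min. With only the 30 min arrays 1, 4 and 7 there were 1002 for the 30 min difference, 4875 for 15 against 30 min, 1157 for 60 against 30 min and 240 for total RNA at 30 min, with only 2, 5 and 8 478 for the 30 min difference and 1092 for total RNA at 30 min, and with only 3, 6 and 9 957 for total RNA at 30 min. Averaging these sets to 3 values per group gave 0 for the 30 min difference, 520 for 60 against 30 min and 44 for total RNA at 30 min, with 2854 at an unadjusted p below 0.05 for the first in limma. Fewer arrays were fitted in these settings, and the cause of the higher counts was not tested. Leaving out 1 array at a time gave 777 to 2684 calls for p/tc, 0 to 306 calls for the 2F difference, 1379 to 4447 calls for the 30 min difference, 53 to 114 calls for total RNA at 30 min, 37 to 2371 calls for total RNA at 60 min. For the 2F difference the count was 0 without any 1 of the 6 arrays of 2F, without total RNA replicate 3 or without newly transcribed RNA replicate 2 of the other 60 min arrays, where limma gave 1286 to 2740 at an unadjusted p below 0.05. Elsewhere it moved no count by 1.5 times.

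Against the total RNA of the 2F arrays p/tc reversed for Trib3 (-0.0339) and for the stress response as a list (camera adjusted p = 0.15), the reference arrays being others by construction. The planned median half-life of 1732 min became 770 with a robust line, 73.6 with the line of nt/tc on p/tc, 835 with a mean log2 of 5 or more, 125 from 1 minus the scaled p/tc and 2896 with a replicate block of same-numbered arrays. Without the 2 arrays named before it was 457, with total RNA replicate 1 alone 431, and with the 2F arrays 346, 164 with the reverse line and 336 with total least squares. It was 658 to 11048 without single replicates, with no value without replicate 1 or at a mean log2 of 9 or more, where the line rose. In the self-test, spread between arrays as in the 60 min data alone lengthened a simulated median of 298 min to 1215 min. The correlation of enrichment was 0.742 between 30 min and 60 min and 0.883 between 30 min and 2F without a filter, and 0.908 for 30 min and 60 min without the 2 arrays. Enrichment at 30 min with actinomycin D at 2 h gave -0.668 with 1 probe set per gene. At 60 min with actinomycin D at 1 h it gave -0.387 at a mean log2 of 7 or more, -0.502 with 1 probe set per gene and -0.331 without the 2 arrays. The cause of these was not tested. The filter at an intensity of 32 is on the mean over arrays, so changes of genes that lay below it in a group are of uncertain size, and transcripts dim throughout were not tested. Small changes were missed where arrays of a group differed, and the self-test recovered 38.8% of changes of 1.5 log2 for nt/tc at 60 min.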

Other observations

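The genes to which the first of these paragraphs refers were picked after their values were seen, and so was the second test of the hypothesis in the third, whereas its first test was written before.

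Single genes stood apart from the median of their list. Rpl12 (3.34 ± 0.14) and Rps25 (2.56 ± 0.14) were enriched in newly transcribed RNA at 30 min while the ribosomal proteins had a median of -0.80. The myosin light chain Myl6 (2.57 ± 0.17) was enriched in a list with a median of -0.52. For Rpl12, Rps25 and Myl6 only 1 probe set was tested, with intensities of 202, 404 and 90.4 before actinomycin D. That of the ribosomal protein Rps19 stood at 12722. Whether these dim probe sets detect the mature transcripts was not tested. Within DNA replication the phosphatase Cdc25a (1.92 ± 0.23) lay above total RNA and the replication factor Rfc4 (-1.91 ± 0.12) below it.
Under actinomycin D for 2 h Myl6 fell (-2.01 ± 0.27), as did Cdc25a (-1.45 ± 0.35) and the licensing factor Cdc6 (-1.45 ± 0.17), while Rpl14, a long-lived ribosomal transcript, was at 0.48 ± 0.13 and not called. Among regulators of apoptosis, a list that was not shifted (camera adjusted p = 0.11), Mcl1 (-2.77 ± 0.13), Birc3 (-2.30 ± 0.17) and Birc2 (-1.58 ± 0.18) fell. Myl6, Cdc25a, Birc3 and Birc2 lay below an intensity of 32 at 2 h, so the sizes of their changes are uncertain.

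In 239 genes, probe sets of the same gene were called in opposite directions between newly transcribed and total RNA at 30 min. The hypothesis was that the enriched probe set detects unprocessed RNA. In 96.7% of these genes the enriched probe set was the dimmer one before actinomycin D, but this share is nearly fixed by the way the probe sets were chosen and decides nothing. The enriched probe set fell further than its partner after 2 h of the drug in 77.8% of the genes (72.0 to 82.9), an interval that spans the limit of 75% set for the test, so the hypothesis may hold but was left undecided.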
